A study of Mus musculus with 4 samples.

How the data were processed

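Per the submitters' processing notes, small intestines were flushed, incubated in EDTA, vortexed and digested with TrypLE, and single cells were stained for CD45, CD31, TER-119 and CD326 with DAPI and sorted. Libraries were made with the 10x Chromium Single Cell 3' kit, chemistry v3.1. The counts were used as deposited: they are UMI counts per gene and barcode, not normalised, made with Cell Ranger 7.0.0 (set A) and 7.1.0 (set B) per the file headers, and on genome build mm10 per the submitters' processing notes. Aligner settings, counting of introns and the options for calling cells are not given in the sources used here. The series title names acute colitis, but no label of the samples names a colitis treatment. Gene coordinates came from GENCODE vM21, which gave a place to all 308 genes looked up. The 2 sets differ in Cell Ranger version and in whether the titles state a sex, so the set is treated as a batch. The replicate numbers used here are not in the labels.

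Barcodes were kept with at least 500 genes, at least 1000 UMIs and under 30% mitochondrial UMIs, unless scrublet, run per library in scanpy 1.11.5, called them doublets. The automatic scrublet threshold called 0.0778%, 15.9%, 0% and 3.66% of barcodes in wild type 1, mutant 1, wild type 2 and mutant 2. After that was seen, the threshold was set per library to call 0.8% of barcodes per 1000 barcodes, which called 246, 1364, 1059 and 1060. Barcodes with 30% or more mitochondrial UMIs were 11.9%, 6.85%, 23.3% and 19.1% in the same order. Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes, chosen within libraries and without mitochondrial, ribosomal and sex-linked genes, were centred within each library, with values limited to 10 SD. Then 50 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9, resolution 1.0) gave 24 clusters. Each was named from markers of 15 cell types among its 50 leading genes, with at least 3 markers needed, and 5 clusters stayed without a name. The T cell or intraepithelial lymphocyte cluster was removed (39, 62, 14 and 36 cells), which left 4258, 10100, 7273 and 7605 epithelial cells. With centring within libraries, 7 of 24 clusters had over 90% of cells from 1 library (2 stem-like, 1 cycling-like, 1 goblet and 3 without a name), against 1 of 24 without centring. The goblet cluster held 1538 cells, 1401 of them from mutant 1.

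For each group of cells, UMIs were summed per library and tested for mutant against wild type with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3), TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment over the genes tested, and genes were called at an adjusted p under 0.05. The summed UMIs ran from 87084400 to 100828000 per library in all epithelial cells, from 32270800 to 40856900 in crypt cells, from 6309280 to 19572500 in enterocytes and from 505746 to 1133130 in tuft cells. DESeq2 1.42.0 was run on the same sums. The fit fixed beforehand has no term for the set and leaves 2 residual degrees of freedom. The fit with the set as a replicate block was an alternative fixed beforehand and leaves 1, with the spread borrowed from a trend over all genes. Whether the genotype effect differs between sets cannot be tested with 1 library per genotype and set. These 2 fits, the gene lists, the cell type markers, the rule for naming genes and the filters on cells other than the doublet threshold were fixed before the data were examined. Giving genes from the fit with the set term a place in the report was decided after the data were seen.

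The rule for named genes covers all epithelial cells, enterocytes and crypt cells. It takes up to 10 genes per direction past the threshold, with the same sign in both sets and a mean of at least 10 CPM. A direction with fewer than 5 is filled to 5 with genes of at least 50 CPM that have the largest smaller value of the 2 within-set ratios, given as values only. Up to 4 members of each list with the smallest p are examples, and all 13 mtDNA-encoded mRNAs and 5 sex-linked genes can be named. Genes of other classes lie outside this rule. The 40 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, then with an estimated correlation and with fry. Members of a list were also adjusted over the list alone. List symbols absent from the files, such as 17 alternate symbols of complex V, were dropped.

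Shares of classes were tested in edgeR on cell numbers with the number of epithelial cells as library size, and in an exact two-sided permutation test. Intervals of single shares are exact Clopper-Pearson 95% binomial intervals. Sums of marker genes are in CPM (counts scaled to the summed UMIs of the library). The fits were tested on simulated data with sets that differ as in these libraries. In all epithelial cells the fit without the set term found 0 of 100 genes changed 2-fold and 77 of 100 changed 4-fold, with 0 false calls. The fit with the set term found 100 of 100 of each, with 13 false calls among 213. A simulated list of the TCA cycle moved 1.5-fold was called, and 0 other lists were. Simulated genes were drawn independently of each other, and each simulated change was the same in both sets. The simulations therefore do not test lists whose genes move together or changes that differ by set. The simulated list was tested at the preset correlation only, so the power with an estimated correlation or by fry was not measured. In all epithelial cells the estimated correlation was 0.50 for the mtDNA-encoded mRNAs and 0.25 for nuclear complex I subunits. The log2 differences between genotypes correlated at 0.0659 across genes between the 2 sets in all epithelial cells, 0.0872 in crypt cells and -0.0104 in enterocytes, and genes are not independent replicates. Alternatives tried were DESeq2's normalization, no filter on low counts, thinned counts, mitochondrial genes left out, other limits on mitochondrial UMIs, doublets kept, other clustering resolutions, no centring, and leaving out each library in turn. Leaving out a library was done without the set term, and it leaves the genotypes unbalanced over the sets. A call lost or a sign changed in that way, for a gene, a list or a share, can therefore come from the difference between sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used elsewhere.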

Results

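Single-cell RNA sequencing was performed on epithelial cells of the small intestine of mice aged 25 weeks, sorted by flow cytometry before capture. The 4 libraries fall into 2 genotypes with n = 2 each: wild type, and mice with the point mutation G5081A in TrnA, the mitochondrial gene for the alanine tRNA. In the mm10 annotation, position 5081, counted from base 1 of mitochondrial chromosome M, lies in mt-Ta (ENSMUSG00000064347, M:5018 to 5086, minus strand). Per the labels, the mutation load was 77% in mutant 1 and 81% in mutant 2. The tRNA is not among the 32285 features, so neither its level nor the load was measured here. Wild type 1 and mutant 1 have no sex in their titles and are called set A. Wild type 2 and mutant 2 are titled male and are called set B, and the file headers give a different Cell Ranger version for each set. In all 4 libraries Xist had 8 to 21 UMIs, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 2001 to 8000 each, so no difference in sex between the sets was seen. The tables hold 5974 (wild type 1), 13805 (mutant 1), 12398 (wild type 2) and 12399 (mutant 2) barcodes, with 99772712, 127796409, 112430029 and 119029754 UMIs in that order of libraries. After filtering, 4297, 10162, 7287 and 7641 cells remained, with a median of 20403, 9458, 10711 and 10402 UMIs per cell, so wild type 1 had the fewest and the deepest cells. The labels do not say whether the libraries come from separate animals, so p-values measure only the spread between these samples.

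The mutated tRNA serves translation of the 13 mtDNA-encoded respiratory chain proteins, so their mRNAs were compared before other genes. In all epithelial cells, mt-Cytb (cytochrome b of complex III) had a log2 ratio of mutant to wild type of 0.45 (SE 0.23, 0.44 in set A and 0.46 in set B). The complex I subunit mt-Nd1 had 0.37 (SE 0.24, 0.36 and 0.38), and mt-Co2, a subunit of cytochrome c oxidase, had 0.25 (SE 0.21, 0.37 and 0.13). The 2 sets went opposite ways for mt-Nd3, with 1.14 in set A and -0.10 in set B, and for mt-Nd6, with 0.39 and -0.34. For mt-Co1 the log2 ratio was -0.15 (SE 0.34), and the others were mt-Atp6 at 0.20, mt-Nd4l at 0.18, mt-Co3 at 0.12, mt-Nd4 at 0.06, mt-Atp8 at 0.06, mt-Nd2 at 0.03 and mt-Nd5 at -0.04. In edgeR, 0 of the 13 passed an adjusted p under 0.05 with or without a term for the set, and without it 0 had an unadjusted p under 0.05. As a list, the 13 mRNAs were called upward by camera (adjusted p = 0.0113, median log2 0.12, 0.36 in set A and -0.05 in set B), and the adjusted p was 0.748 with an estimated correlation. The call was lost without wild type 1 (adjusted p = 0.629) and without mutant 2 (adjusted p = 0.472).

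**Figure D1:**
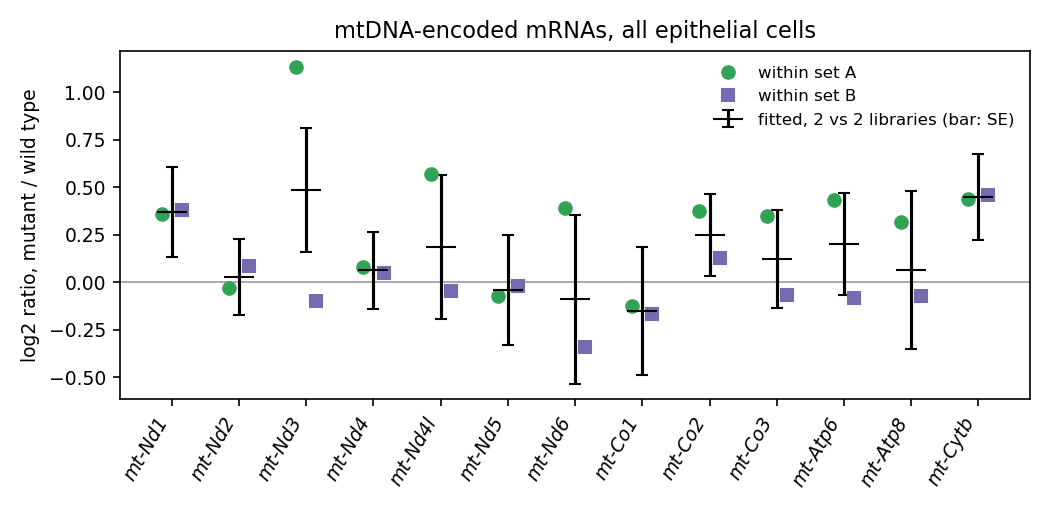
Log2 ratio of mutant to wild type (y axis) of the 13 mtDNA-encoded mRNAs (x axis) in all epithelial cells, as the fitted value with its SE and as the ratio within set A and within set B. mt-Cytb and mt-Nd1 lie at 0.45 and 0.37 with like values in both sets, while mt-Nd3 lies at 1.14 in set A and -0.10 in set B.

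Mitochondrial genes took 4.86% of UMIs in wild type 1 (exact 95% binomial interval 4.85% to 4.86%), 5.61% in mutant 1 (5.60% to 5.61%), 5.31% in wild type 2 (5.31% to 5.32%) and 5.01% in mutant 2 (5.01% to 5.02%). These intervals cover counting error only. The means were 5.08% (SD 0.323, n = 2) for wild type and 5.31% (SD 0.422, n = 2) for mutants, and an exact two-sided permutation test gave p = 0.667, where 0.333 is the smallest p the design allows. Within set A the mutant was 0.753 percentage points above wild type, and within set B the difference was -0.300. The difference of the means, 0.227, was -0.00162 without wild type 1, -0.0714 without mutant 1, 0.455 without wild type 2 and 0.525 without mutant 2. It also depends on the limit on mitochondrial UMIs, which acts on the share itself. With all 4 libraries it was 0.284 under 15%, 0.0535 under 50% and -0.0376 with no limit. Among nuclear genes of mitochondria, the mitochondrial ribosomal proteins lay higher in mutants of both sets in 50 of 78 members and lower in both in 4 (median log2 0.10, camera adjusted p = 2.52e-06, and adjusted p = 0.713 with an estimated correlation). This list kept its upward call without each of the 4 libraries in turn (adjusted p = 0.000228 to 0.0181). Nuclear subunits of complex I were higher in both sets in 25 of 36 members and lower in both in 0 (median log2 0.11, camera adjusted p = 0.000322, and 0.713 as the adjusted p with an estimated correlation). For complex IV it was 11 of 13 members (adjusted p = 0.0161, and 0.748 with an estimated correlation), for complex V 8 of 17 (adjusted p = 0.0334, and 0.717 with an estimated correlation) and for the TCA cycle 12 of 17 (adjusted p = 0.02, and 0.713 with an estimated correlation). No member of these lists passed the threshold over all genes or adjusted over the list alone, and without wild type 1 the adjusted p of the complex I, IV and V lists was 0.55, 0.768 and 0.768. Without mutant 2 it was 0.96, 0.38 and 0.839, and for the TCA cycle it was 0.173, 0.135 and 0.642 without mutant 1, mutant 2 and wild type 2. Lists not called were complex II (adjusted p = 0.308), complex III (0.161), mitochondrial aminoacyl-tRNA synthetases (0.824), mitochondrial chaperones and proteases (0.652), mitochondrial biogenesis (0.387) and mitophagy and dynamics (0.577).

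In all epithelial cells together, Paneth cell defensins were higher and an intestinal detoxifying enzyme and a villus protein were lower in mutants of both sets. In the fit with the set as a term, 5 defensin genes rose. Defa34 (8:21665797 to 21666732) rose by a log2 ratio of 1.14 (SE 0.14, adjusted p = 0.0114), Defa20 by 1.08, Defa35 by 1.09, Defa32 by 1.06 and Defa5 by 0.97 (SE 0.14, adjusted p = 0.0303). Defensin genes are near copies of each other, so reads can be shared among them and the identity of each is uncertain. The Paneth cell share of cells had log2 ratios of 1.62 in set A and -0.25 in set B. Within Paneth cells these 5 genes had medians of 0.01 in set A and 0.80 in set B. The part of the share in the rise was not tested. The lipid droplet protein gene Hsd17b13 (5:103955440 to 103977410) rose by 1.26 (SE 0.17, adjusted p = 0.0215). Acta1, skeletal muscle actin, rose by 1.38 (SE 0.22, adjusted p = 0.0467, 0.84 in set A and 1.85 in set B). Cyp3a11, a cytochrome P450 that oxidises drugs and bile acids (5:145854426 to 145879964), fell by a log2 ratio of 1.04 (SE 0.15, adjusted p = 0.0289). Clca4a, a chloride channel accessory gene of the villus tip list (3:144952480 to 144975045), fell by 0.83 (SE 0.12, adjusted p = 0.0326). In set A and set B, Cyp3a11 had -0.85 and -1.20 and Clca4a -0.90 and -0.76, beside log2 ratios of -0.83 and -0.01 for the enterocyte share of cells and -0.21 and 0.17 for summed enterocyte markers. The heat shock genes Hspa1a and Hspa1b, near copies of each other, fell by 2.57 (SE 0.38, -1.57 in set A and -2.85 in set B) and 2.02 (SE 0.27, -1.52 and -2.36), and Hspa1a had 26, 8, 162 and 20 UMIs in wild type 1, mutant 1, wild type 2 and mutant 2. Values short of the threshold, from the fit without the set term and with the same sign in both sets, were the mucus genes Zg16 at -0.70 (SE 0.25) and Fcgbp at -0.62 (SE 0.23), S100a6 at -0.50 (SE 0.16) and the potassium channel gene Kcnb2 at -0.51 (SE 0.21). Zg16, Fcgbp and S100a6 are leading genes of goblet cluster 0, and Kcnb2 of an enteroendocrine cluster at resolution 0.5. In set A and set B the goblet share of cells had log2 ratios of -0.24 and -0.19. The enteroendocrine share had -0.21 and -0.47. The part of these shares in the 4 values was not tested.

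These calls rest on the term for the set. In the fit fixed beforehand, which has no such term, edgeR called 0 of 16696 genes (108 with an unadjusted p under 0.05), and DESeq2 called 8. With the set as a term, edgeR called 21 (12 up, 9 down), all with the same sign in both sets, and 19 of them were also called by DESeq2 with that term. That fit favours genes on which the sets agree, so the shared sign is not separate support. Across all genes tested, the log2 differences between genotypes correlated at 0.0659 between the 2 sets. Paneth markers, 14 genes of which most are themselves defensins, summed to 30208 CPM in wild type 1, 49436 in mutant 1, 89034 in wild type 2 and 107859 in mutant 2. With reads shared among defensins, these sums are not separate evidence. Without mutant 2, Acta1 had a log2 ratio of -0.13, and without wild type 2 Clca4a had 0.37 and Cyp3a11 0.61, each in the fit without the set term. Such a fit compares genotypes that are not balanced over the sets, so these signs can come from the difference between sets. Within set A and set B, Acta1 had 0.84 and 1.85, Clca4a -0.90 and -0.76 and Cyp3a11 -0.85 and -1.20.

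Of the 40 gene lists fixed beforehand, 20 were called in all epithelial cells, 15 up and 5 down, and with an estimated correlation the adjusted p of these calls ran from 0.713 to 0.748, so none was kept. The power of that test with these few libraries was not measured, so a call lost in it does not show that a list did not move. Genes of the integrated stress response, which ATF4 switches on when translation is impaired, were higher in both sets in 19 of 30 members and lower in both in 3 (camera adjusted p = 4.27e-11). Their median log2 ratio was 0.32, with 0.21 in set A and 0.28 in set B. With the set as a term 0 of them passed over all genes, and 8 rose when adjusted over the list alone. Examples as values from the fit without the set term were the serine synthesis genes Psat1 at 0.84 (SE 0.18) and Psph at 0.57 (SE 0.18). Chac1, which degrades glutathione, stood at 1.00 (SE 0.41). Goblet and mucus genes were lower in both sets in 12 of 20 members (adjusted p = 8.65e-08). Their median was -0.50 in set A and -0.14 in set B, and 9 fell with the set as a term when adjusted over the list alone. Summed goblet markers, most of which belong to that list, had a log2 ratio of -0.62 in set A and -0.44 in set B. The goblet share of cells had -0.24 and -0.19, and its part in the list's values was not tested. Without wild type 1 the goblet list was no longer called (adjusted p = 0.748), while the stress response list kept its call without each library (0.0105 at most). Interferon-stimulated genes (adjusted p = 2.67e-12), MHC class II (0.000495), MHC class I (0.00106) and antimicrobial genes (0.0146) were called up, but their medians went opposite ways in the 2 sets. They were -0.24, -0.28, -0.13 and -0.24 in set A against 1.01, 1.11, 0.61 and 0.35 in set B. Without wild type 2 the MHC class II list was called downward (adjusted p = 0.0339) and MHC class I was not called (0.109). Without mutant 2 the antimicrobial list was called downward (adjusted p = 0.0246), and interferon, MHC class I and MHC class II were not called (0.466, 0.085 and 0.0938). Without wild type 1 the antimicrobial list was not called (0.55).

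The other lists called upward were cytosolic ribosomal proteins (46 of 64 higher in both sets, adjusted p = 2.34e-06), G2 and M phase genes (21 of 26, adjusted p = 1.55e-05), cholesterol synthesis (13 of 22, adjusted p = 0.0113) and antioxidant genes (11 of 24, adjusted p = 0.0493). The G2 and M phase call stands beside cycling-like cells at 1.64% of wild type 1 and 17.9% of mutant 1, and summed cycling markers had log2 ratios of 0.39 in set A and -0.19 in set B. Those called downward were villus tip genes (adjusted p = 0.00268, -0.50 in set A and -0.05 in set B), immediate early and dissociation genes (0.00971, -0.31 and 0.08), regenerative or fetal-like genes (0.0113, -0.41 and 0.07) and stem cell genes (0.0327, 0.07 and -0.20). The villus tip medians move by set as the enterocyte share does (-0.83 and -0.01). The adjusted p with an estimated correlation was 0.713 for these except cholesterol synthesis (0.748). Each of these 8 calls was lost without at least 1 library. Without wild type 1 this was so for cytosolic ribosomal, antioxidant, regenerative and immediate early genes (adjusted p = 0.256, 0.315, 0.878 and 0.856). Without mutant 1 it was so for G2 and M phase, cholesterol synthesis, antioxidant, villus tip, regenerative and stem cell genes (0.6, 0.741, 0.0521, 0.28, 0.347 and 0.106). Without wild type 2 it was so for cholesterol synthesis, antioxidant, villus tip and stem cell genes (0.95, 0.109, 0.42 and 0.95). Without mutant 2 it was so for cytosolic ribosomal, antioxidant, regenerative, immediate early and stem cell genes (0.0562, 0.38, 0.0562, 0.703 and 0.313). The remaining lists were not called: sugar and amino acid digestion (adjusted p = 0.0647), NF-kB and cytokines (0.0731), iron handling (0.093), p53 targets (0.18), S phase (0.206), endoplasmic reticulum stress (0.287), glycolysis (0.477), fat uptake (0.575), junctions (0.652), lower villus genes (0.684), proximal and distal intestine genes (0.725 each), fatty acid oxidation (0.877) and sex-linked genes (0.914). The median, the mean and the test had the same sign in the called lists, but differed in sign in 2 lists not called in all epithelial cells, 5 in enterocytes and 2 in crypt cells. For fatty acid oxidation the median was 0.00, the mean -0.04 and the test upward. By fry, 0 of the 40 lists were called in any of the 3 groups of cells tested.

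**Figure D2:**
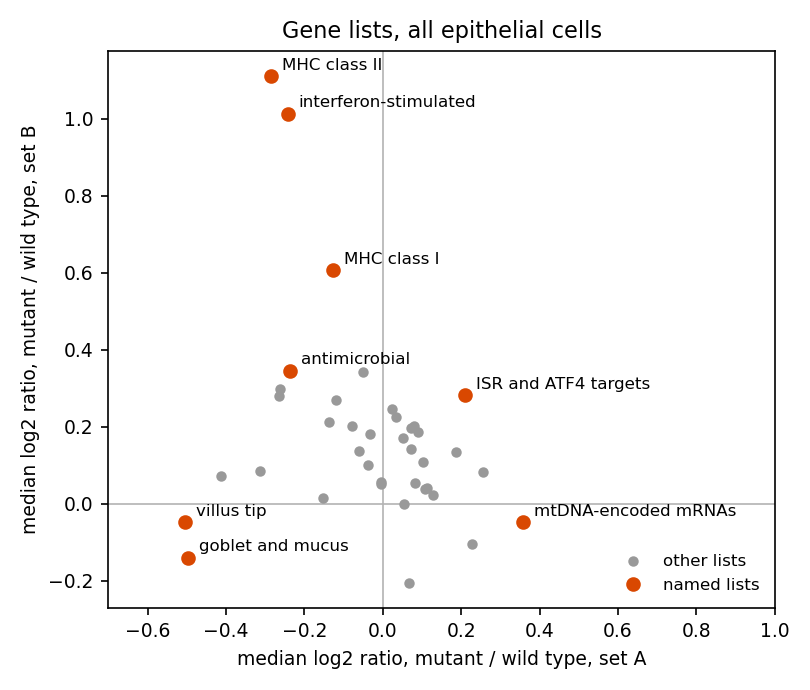
Median log2 ratio of mutant to wild type within set A (x axis) and within set B (y axis) for 39 gene lists in all epithelial cells, each point a list. The stress response and ATF4 list lies above 0 in both sets (0.21 and 0.28), and the MHC class II and interferon lists lie at -0.28 and -0.24 in set A but 1.11 and 1.01 in set B.

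Crypt cells, here the stem-like and cycling-like clusters together, were compared to ask whether the proliferating compartment differs by genotype. With the set as a term, 80 genes were called (45 up, 35 down), all with the same sign in both sets, which that fit favours. The balance of directions depends on the filters, with 13 up and 65 down with automatic doublets and 37 up and 7 down under 15% mitochondrial UMIs. The same edgeR fit called 0 of 13368 genes in stem-like cells alone and 0 of 13240 in cycling-like cells alone. DESeq2 with the set term called 13 and 6 there. The mix of these classes differed within set A, and its part in the 80 calls was not tested. Some genes of the integrated stress response rose. Chac1 (2:119351229 to 119354381) rose by 2.56 (SE 0.39, adjusted p = 0.00133). Aldh1l2, a mitochondrial folate enzyme (10:83487450 to 83534140), rose by 2.99 (SE 0.59, adjusted p = 0.0147). Psat1 (19:15904678 to 15947337) rose by 0.69 (SE 0.13, adjusted p = 0.0126) and Psph (5:129765558 to 129787449) by 0.66 (SE 0.13, adjusted p = 0.0105). Of the 29 members measured, 6 passed over all genes and 11 when adjusted over the list alone, and 18 were higher in both sets against 3 lower in both. Chac1 and Aldh1l2 are scarce, with 6, 77, 17 and 61 UMIs for Chac1 and 4, 21, 2 and 30 for Aldh1l2 in wild type 1, mutant 1, wild type 2 and mutant 2. The mutant to wild type ratio of these counts was 5.43 (exact 95% interval, for counting error only, 3.48 to 8.85) for Chac1 and 7.69 (3.30 to 21.9) for Aldh1l2. Camera called the list up (adjusted p = 1.17e-17, and an adjusted p of 0.632 with an estimated correlation). Its median log2 ratio was 0.25 in set A and 0.36 in set B. It was called up without each library in turn (3.42e-06 at most).

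Paneth cell transcripts were higher in the sums of crypt cells. Defa34 rose by 1.26 (SE 0.13, adjusted p = 2.8e-05). Its log2 ratio was 1.24 in set A and 1.27 in set B. Defa5, Defa20, Defa36, Defa22, Defa21, Defa3, Defa26 and Defa29 rose by 0.87 to 1.34. In the fit without the set term, Defa29 had -0.31 without mutant 2. Outside the defensins, the lectin gene Mptx2 rose by 1.00 (SE 0.13), the antimicrobial ribonuclease gene Ang4 by 0.84 (SE 0.11, adjusted p = 0.000277) and lysozyme, Lyz1, by 0.84 (SE 0.12, adjusted p = 0.000695). Of 21 antimicrobial genes, 8 rose over all genes and 9 when adjusted over the list alone. Camera called the list up (adjusted p = 5.66e-07, and 0.632 with an estimated correlation), with a median of -0.07 in set A and 0.58 in set B. Without mutant 2 its adjusted p was 0.722. Summed Paneth markers in crypt cells, which include many of the genes just named, had log2 ratios of 1.05 in set A and 0.50 in set B. These transcripts made up 0.149% to 0.678% of UMIs in crypt cells against 58.2% to 67.6% in Paneth cells. In barcodes under 1000 UMIs, which were not kept as cells here, they made up 4.17%, 3.06%, 2.11% and 4.13% in wild type 1, mutant 1, wild type 2 and mutant 2. Expression by crypt cells themselves was not shown.

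Some goblet cell genes were lower in crypt cells, with values that depend on the clustering. The mucin chaperone gene Agr2 (12:35992907 to 36004087) fell by 1.66 (SE 0.34, adjusted p = 0.0192, -2.97 in set A and -0.36 in set B). Clca1 (3:145003817 to 145032776) fell by 0.90 (SE 0.13, adjusted p = 0.000717), and Atoh1, which specifies secretory cells, by 0.90 (SE 0.18, adjusted p = 0.0171). Tff3, Zg16, Fcgbp and Guca2a also fell, by 0.77, 0.74, 0.75 and 1.10. Of 19 goblet and mucus genes, 9 fell over all genes and 16 when adjusted over the list alone (1 rose on that scale). Camera called the list down (adjusted p = 1.1e-24, and an adjusted p of 0.632 with an estimated correlation), with a median of -1.03 in set A and -0.36 in set B. Summed goblet markers had a log2 ratio of -1.43 in set A and -0.51 in set B, but most of them are members of this list, so this adds no separate evidence. When cells were clustered without centring within libraries, the goblet list was not called (adjusted p = 0.483). Agr2 then had a log2 ratio of -0.01 in set A and 0.09 in set B. In set A Clca1 had 0.17, Atoh1 0.34 and Tff3 0.44 without centring, while Defa34 had 1.30. Guca2a, Zg16, Fcgbp, Hepacam2, Plcb1 and Creb3l1 also stood above 0 in set A without centring, at 0.15, 0.01, 0.14, 0.22, 0.32 and 0.18. In set B without centring, Clca1, Atoh1 and Tff3 had -0.15, -0.10 and -0.30, and these 6 had -0.26, -0.59, -0.29, -0.33, -0.05 and -0.22.

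**Figure D3:**
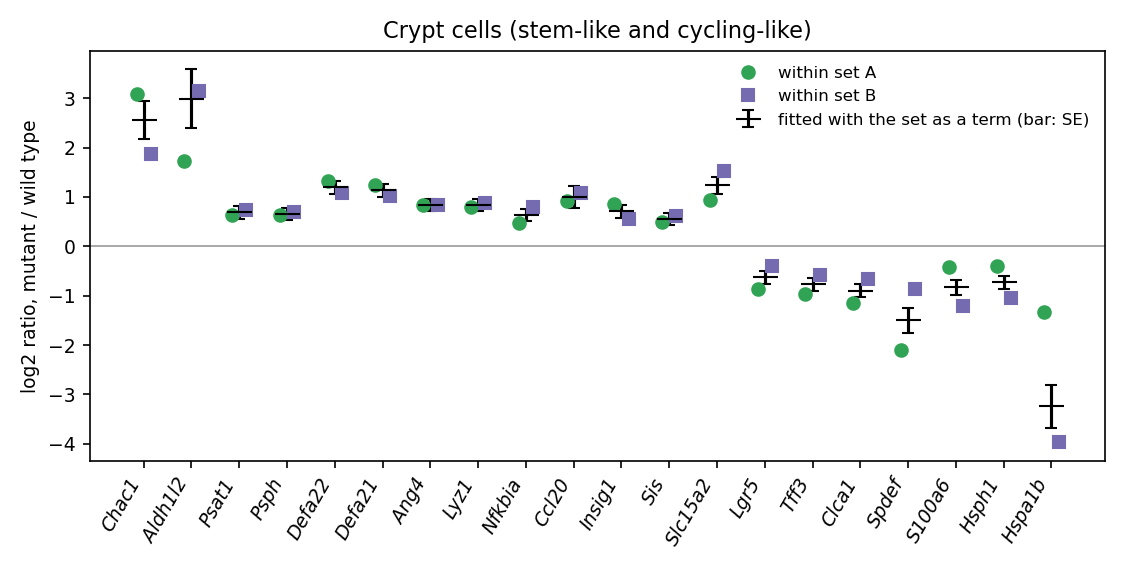
Log2 ratio of mutant to wild type (y axis) of 20 named genes (x axis) in crypt cells: the fitted value with the set as a term and its SE, and the ratios within set A and within set B. Chac1 and Lyz1 lie at 2.56 and 0.84, and Lgr5, Tff3 and Clca1 at -0.63, -0.77 and -0.90, and without centring within libraries Tff3 and Clca1 have the other sign in set A.

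Among other genes of crypt cells, the stem cell receptor gene Lgr5 (10:115450311 to 115587780) fell by 0.63 (SE 0.13, adjusted p = 0.0169, -0.87 in set A and -0.40 in set B, and -0.91 and -0.39 without centring). The mix of crypt cells differed in set A: stem-like cells were 1101 of 1171 in wild type 1, 1843 of 3652 in mutant 1, 1278 of 2253 in wild type 2 and 1300 of 2353 in mutant 2. Stem cell genes were lower in both sets in 11 of 20 members and called down (adjusted p = 0.000131, and 0.632 with an estimated correlation), a call lost without mutant 1 (0.219) and without wild type 2 (0.0674). The NF-kB inhibitor gene Nfkbia rose by 0.64 (SE 0.12) and the chemokine gene Ccl20 by 1.00 (SE 0.22), in a list higher in both sets in 14 of 18 members (adjusted p = 4.04e-08, and 0.632 with an estimated correlation, lost without wild type 2 at 0.159). Insig1, which restrains cholesterol synthesis, rose by 0.71 (SE 0.13), the sucrase-isomaltase gene Sis by 0.55 (SE 0.11) and the peptide transporter gene Slc15a2 (16:36750177 to 36784962) by 1.24 (SE 0.17, adjusted p = 0.000307). The heat shock genes Hsph1 and Hspa1b fell by 0.73 (SE 0.13) and 3.25 (SE 0.43). Wild type 2 held most of the UMIs of Hspa1b (24, 10, 304 and 16 in wild type 1, mutant 1, wild type 2 and mutant 2), with -1.32 in set A and -3.96 in set B. Without wild type 2 Hsph1 had 0.17 in the fit without the set term. Of other genes, S100a6 fell by 0.83, Plcb1 by 1.03, Selenom by 1.00, Hepacam2 by 0.95, Creb3l1 by 0.80 and Arhgap24 by 0.79. Without centring, Selenom had -0.13 in set A and 0.39 in set B, S100a6 0.03 and -1.40, and Arhgap24 -0.85 and -0.23. The mtDNA-encoded mRNAs were called up (adjusted p = 0.0292, and 0.693 with an estimated correlation), with a median of 0.37 in set A and -0.12 in set B, a call lost without mutant 1 (0.973) and without wild type 1 (0.749). mt-Cytb at 0.45 (SE 0.12) was their 1 member to rise when adjusted over the list alone. Interferon-stimulated genes were called up (adjusted p = 7.87e-11, and 0.693 with an estimated correlation), with -0.15 in set A and 0.86 in set B, and the call was lost without mutant 2 (0.527) and without wild type 2 (0.278). In all, camera called 18 lists in crypt cells (15 up, 3 down), with adjusted p values of 0.632 to 0.721 with an estimated correlation. At the preset correlation with the set as a term it called 21 (17 up, 4 down), and 17 of the 18 were among them in the same direction. Without centring 12 of the 18 kept their call. Those lost were the mtDNA-encoded mRNAs (adjusted p = 0.0971), complex I (0.0569), complex IV (0.0936), iron handling (0.0921), endoplasmic reticulum stress (0.786) and goblet genes (0.483).

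Without the set term edgeR called 0 of 14521 genes in crypt cells (131 with an unadjusted p under 0.05) and DESeq2 called 0. Of the 80 genes called with it, 34 were also called by DESeq2 with that term. The stem-like cells came mostly from different clusters in each library: cluster 2 held 94.0% of those of wild type 1, cluster 8 held 99.8% of those of mutant 1, and cluster 16 held 99.3% and 99.5% of those of wild type 2 and mutant 2. Without centring, 86 genes were called with the set term, and 53 of the 80 were among them with the same sign.

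Enterocytes, the absorptive cells, were compared next, and their gene values are given without a call, since edgeR passed 0 of 12031 genes with or without the set term (186 with an unadjusted p under 0.05 without it, and DESeq2 called 0). Among genes of at least 50 CPM, the largest values shared by both sets were Acta1 at 1.72 (SE 0.54), Defa5 at 0.98 (SE 0.20), Defa22 at 0.91 (SE 0.32), Mptx2 at 0.85 (SE 0.20) and the cold-inducible RNA-binding protein gene Rbm3 at 0.76 (SE 0.27). In the other direction were Cyp3a11 at -1.19 (SE 0.32), Slc23a4, of the nucleobase and ascorbate transporter family, at -1.03 (SE 0.19), Clca4a at -0.89 (SE 0.26), Fhit at -0.88 (SE 0.22) and the nucleoside transporter gene Slc28a2 at -0.79 (SE 0.22). Camera called 15 lists (13 up, 2 down), each with an adjusted p of 0.781 with an estimated correlation. Villus tip genes were lower in both sets in 8 of 14 members and higher in both in 0 (adjusted p = 9.85e-07, -0.54 in set A and -0.20 in set B). The ectonucleotidase gene Nt5e stood at -0.52 (SE 0.19), and the call was lost without wild type 1 (adjusted p = 0.0901). Clca4a, Slc23a4, Slc28a2 and Nt5e are leading genes of enterocyte cluster 9, which held 270 of 940 enterocytes in wild type 1, 365 of 1251 in mutant 1, 1229 of 2708 in wild type 2 and 863 of 2810 in mutant 2. The median mitochondrial share of enterocytes was 7.43%, 7.25%, 15.3% and 11.9% in that order, and the part of either in these values was not tested. Stress response genes were higher in both sets in 17 of 26 members (adjusted p = 2.79e-06, lost without wild type 2 at 0.168). Psat1 stood at 1.85 (SE 0.51, 4 and 15 UMIs in wild type 1 and 2, 23 and 44 in mutant 1 and 2), Atf5 at 1.55 (SE 0.60) and Asns, asparagine synthetase, at 0.96 (SE 0.29). With the set as a term 4 of them rose when adjusted over the list alone.

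Interferon-stimulated genes in enterocytes were higher in both sets in 19 of 35 members (adjusted p = 2.85e-14, median 0.02 in set A and 0.95 in set B). Dhx58 stood at 1.31 (SE 0.32), Usp18 at 1.01 (SE 0.33) and Bst2 at 0.99 (SE 0.34). With a term for the set, 14 rose when adjusted over the list alone. This call was lost without wild type 2 (0.195). Cytosolic ribosomal proteins (50 of 64 higher in both sets, adjusted p = 4.56e-13), mitochondrial ribosomal proteins (49 of 78, 3.17e-08) and complex I (29 of 36, 9.66e-05) were called up. Their medians were larger in set A (0.63, 0.38 and 0.29) than in set B (0.08, 0.09 and 0.15), and stem cell genes in the same sums, a list not called, had 0.65 and -0.24. Without wild type 1 the adjusted p values of the 3 calls were 0.812, 0.763 and 0.557. Without mutant 2 they were 0.129 and 0.991 for the mitochondrial ribosomal proteins and complex I. Antimicrobial genes were called up (adjusted p = 0.000658, lost without mutant 2 at 0.489). Ang4 stood at 0.87 (SE 0.22), Lyz1 at 0.71 (SE 0.23) and the nitric oxide synthase gene Nos2 at -0.84 (SE 0.28). Paneth markers summed to log2 ratios of 0.81 in set A and 0.46 in set B in these cells. G2 and M phase genes were called up (adjusted p = 0.000477, 0.75 in set A and -0.11 in set B), beside summed cycling markers of 306 CPM in wild type 1, 613 in mutant 1, 338 in wild type 2 and 297 in mutant 2. Without mutant 1 that call was lost (0.446). NF-kB genes were called down (adjusted p = 0.0121), but not without mutant 2 (0.571) or wild type 2 (0.444). For the mtDNA-encoded mRNAs the adjusted p was 0.76 and for goblet genes 0.581. The largest group of enterocytes came from cluster 4 in set A (34.5% and 29.5%) and from cluster 9 in set B (45.4% and 30.7%), and the summed depth was 6333080 and 6309280 UMIs in set A against 16918700 and 19572500 in set B.

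**Figure D4:**
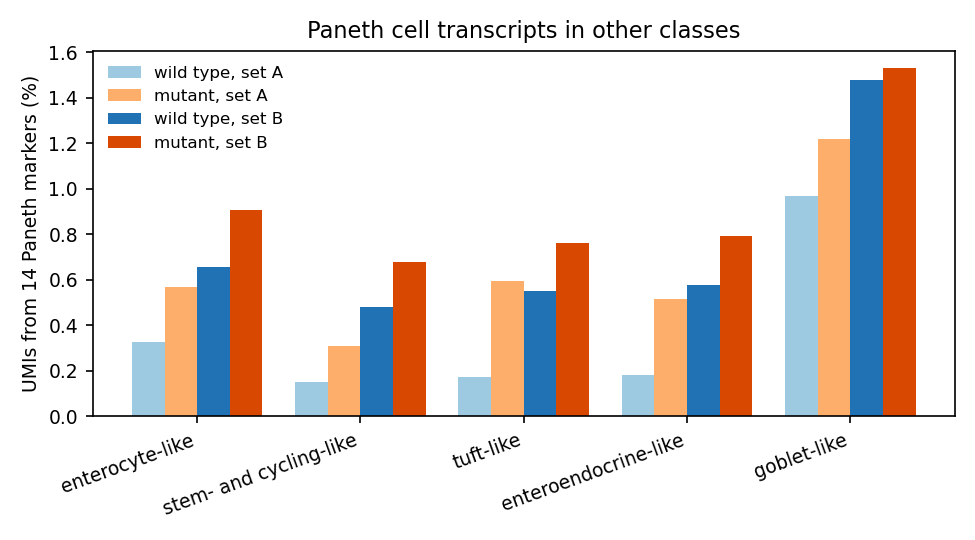
Percentage of UMIs from 14 Paneth marker genes (y axis) in cells of 5 other classes (x axis), 1 bar per library. The crypt cell values run from 0.149% in wild type 1 to 0.678% in mutant 2, and the enterocyte values from 0.325% to 0.908%.

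In the other classes the fit without the set term called 0 genes: 0 of 12731 in goblet cells (264 with an unadjusted p under 0.05), 0 of 10902 in Paneth cells (89), 0 of 8449 in tuft cells (72), 0 of 10884 in enteroendocrine cells (237), 0 of 13368 in stem-like cells (95) and 0 of 13240 in cycling-like cells (352), all by edgeR. DESeq2 called 1 gene in stem-like cells and 0 in the others. With the set as a term, 84 genes were called in enteroendocrine cells (63 up, 21 down), of which 73 had the same sign in both sets, 17 in tuft cells (13 up, 4 down) and 1 in Paneth cells, Acta1, by 2.75, chosen for naming after its values were seen. In goblet, stem-like and cycling-like cells it called 0. Of these, DESeq2 with the set term also called 4 in enteroendocrine and 1 in tuft cells. It further called 13 in stem-like, 6 in cycling-like and 3 in goblet cells. Without centring, edgeR with the set term called 20 in enteroendocrine, 25 in tuft, 4 in Paneth, 11 in goblet and 71 in cycling-like cells. Genes that rose in both enteroendocrine and tuft cells included Defa21, Defa22, Defa34 and Lyz1, chosen after their values were seen, and the summed Paneth markers of tuft cells had log2 ratios of 1.80 in set A and 0.47 in set B. In Paneth cells themselves these sums had -0.15 and 0.06, while the 5 defensins called in all epithelial cells had a median of 0.01 in set A (-0.27 to 0.21) and 0.80 in set B (0.55 to 1.02). Whether these effects differ between classes was not tested. The tests of tuft and enteroendocrine cells rest on few cells, with 39, 72, 97 and 119 tuft cells and 165, 339, 163 and 123 enteroendocrine cells in wild type 1, mutant 1, wild type 2 and mutant 2.

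The makeup of the sorted epithelium was compared by the share of each class. Stem-like cells made up 25.9% of wild type 1 (exact 95% binomial interval 24.5% to 27.2%, for counting error only), 18.2% of mutant 1 (17.5% to 19.0%), 17.6% of wild type 2 (16.7% to 18.5%) and 17.1% of mutant 2 (16.3% to 18.0%). Cycling-like cells made up 1.64% (1.28% to 2.07%), 17.9% (17.2% to 18.7%), 13.4% (12.6% to 14.2%) and 13.8% (13.1% to 14.6%) in the same order, and Paneth cells 0.986% (0.712% to 1.33%), 3.03% (2.70% to 3.38%), 4.18% (3.73% to 4.67%) and 3.52% (3.12% to 3.96%). Enterocytes were 22.1%, 12.4%, 37.2% and 36.9%, goblet cells 22.7%, 19.2%, 11.4% and 9.99%, enteroendocrine cells 3.88%, 3.36%, 2.24% and 1.62%, tuft cells 0.916%, 0.713%, 1.33% and 1.56%, and clusters without a name 22.0%, 25.2%, 12.6% and 15.4%. In edgeR 0 of 8 classes had an unadjusted p under 0.05, and the adjusted p values ran from 0.898 to 0.989, or from 0.475 to 0.853 with the set as a term. The log2 ratio was 1.07 (SE 0.82) for cycling-like cells, 3.45 in set A and 0.05 in set B, and 0.34 (SE 0.82) for Paneth cells, 1.62 and -0.25. Exact permutation tests gave p = 0.333 to 1, where 0.333 is the smallest the design allows. The split of crypt cells into stem-like and cycling-like in wild type 1 changed with the clustering: without centring its cycling-like share was 5.52%, against 9.07%, 11.2% and 11.8% in mutant 1, wild type 2 and mutant 2. With automatic doublets, crypt cells were 2.39% of wild type 1, against 27.5% here. The effect of the sort and of the deeper cells of wild type 1 on these shares was not tested.

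**Figure D5:**
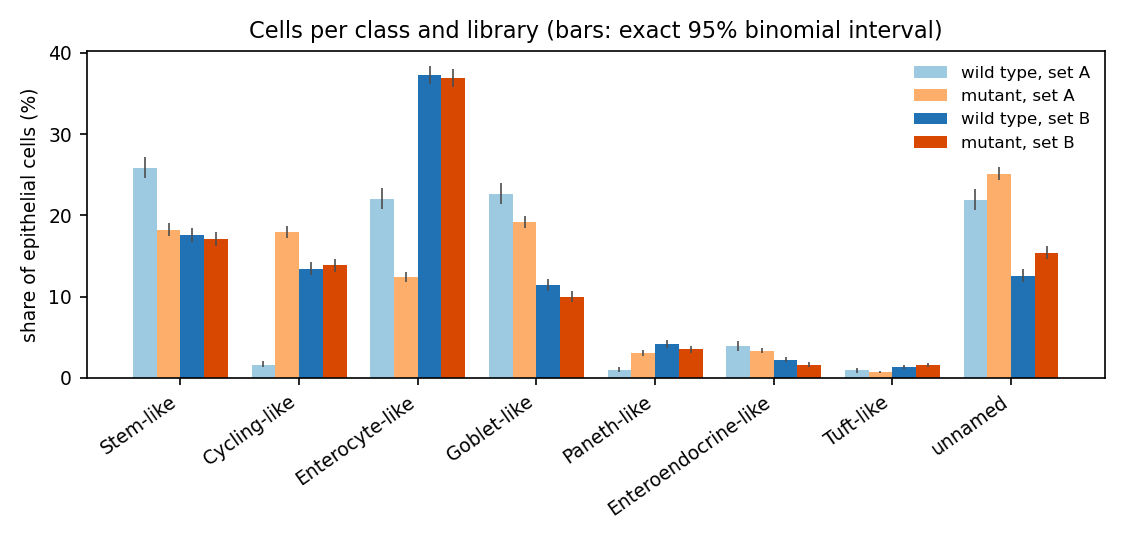
Percentage of epithelial cells in each class (y axis) by class (x axis) and library, with exact 95% binomial intervals for counting error. Cycling-like cells stand at 1.64% in wild type 1 against 13.4% to 17.9% in the other libraries, and enterocytes at 12.4% to 37.2%.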

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

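Of the tests in this part, the bounds for free Paneth RNA over 3 classes were written before its result was seen, and the other tests, those on enterocytes or crypt cells alone included, were chosen after the results they measure were seen.

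Paneth cell transcripts stood higher in mutants in cells of other classes, with summed marker log2 ratios of 0.81 in set A and 0.46 in set B in enterocytes and 1.05 and 0.50 in crypt cells. A larger number of Paneth cells in the mutant library had the sign that cause needs in set A, where the log2 ratio of their share was 1.62. In set B the ratio was -0.246 (4.18% in wild type 2 and 3.52% in mutant 2), which goes against that cause. It was not excluded there, since the binomial intervals of these 2 shares overlap and the shares count kept cells only. More marker RNA relative to the other RNA of Paneth cells was not seen in set A. Against the other UMIs of Paneth cells the median over 14 markers was -0.303 (quartiles -0.551 and -0.151), which argues against that cause. Their UMIs per Paneth cell had -1.92, a value not scaled for depth. Paneth cells had a median of 90573.5 UMIs in wild type 1 (42 cells) and 24603 in mutant 1, so this value cannot decide. In set B that cause stays open, as the ratio to other UMIs was 0.0650 (quartiles -0.00697 and 0.286), under the 0.439 seen in enterocytes. The 5 defensins called in all epithelial cells, picked for that rise, had a median of 0.798 (0.00659 in set A). UMIs per Paneth cell had 0.533 in set B. Depth moved there too, with a median of 35561.5 UMIs per Paneth cell in wild type 2 and 54232.5 in mutant 2. Over 3 classes together, free RNA from Paneth cells could not be told apart from expression in the other classes: the median SD over markers of the ratio to Paneth cells was 0.774, between the bounds of 0.6 and 1.2, on markers with at least 10 UMIs and 50 CPM in Paneth cells, a limit not in the written test. In enterocytes alone free RNA fitted, with SDs of 0.328 to 0.469, while in crypt cells it stays open (0.536 to 1.03). In barcodes under 1000 UMIs, which are called barcodes and not empty droplets, the log2 ratio of the Paneth marker share was -0.45 in set A, against the free RNA account, and 0.97 in set B, with it. An effect of the genotype on Paneth cells remains an untested hypothesis, and the causes may differ between the sets.

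Genes of the integrated stress response stood higher in mutants, with a median in crypt cells of 0.25 in set A and 0.36 in set B. Stress of handling was judged by the immediate early and dissociation list. In set A this list had a median of -0.314 in all epithelial cells and -0.419 in crypt cells (upper quartiles -0.107 and -0.0132). That argues against handling stress of the kind these genes report. Other stress of handling is not measured by them, and set A holds 1 library per genotype, so handling was not excluded. Handling stays open in set B as well, where the list had 0.0836 in all epithelial cells and 0.436, the sign and size that cause needs, in crypt cells. In set B, which does not hold the deeper wild type 1 library, the median in crypt cells was 0.362 (quartiles 0.0275 and 0.743). That argues against this library as the whole cause. Set B holds 1 library per genotype, so this cause was not excluded. Camera also called the list upward without wild type 1, but that fit leaves the genotypes unbalanced over the sets. With all 4 libraries the call was lost with an estimated correlation (adjusted p = 0.632) and by fry (0.929). A different mix of cell classes stays open, with a median above 0 in both sets in 4 of 7 classes, where at most 3 or at least 6 would have decided, although within crypt cells the medians were 0.19 in set A and 0.09 in set B in stem-like cells and 0.10 and 0.45 in cycling-like cells. A mix within these classes stays open too. Of the cycling-like cells, cluster 20 held 84.3% of the 70 of wild type 1 and cluster 21 held 100% of the 1809 of mutant 1. An answer of the cells to impaired mitochondrial translation may be offered as a hypothesis, but it was not tested.

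Goblet and mucus genes stood lower in mutant crypt cells, with a median of -1.03 in set A and -0.36 in set B. A different assignment of secretory cells to the crypt class fitted both sets: without centring within libraries the median was 0.174 in set A and -0.145 in set B. In set A the list's median in enterocytes was 0.0118 (quartiles -0.286 and 0.324, against the -1.03 to be explained). That argues against less free goblet cell RNA in set A. Summed goblet markers in enterocytes had -0.16 there. Set A holds 1 library per genotype, so this cause was not excluded. In set B the list's median in enterocytes had the size this cause needs (-0.204). The lower goblet values in crypt cells may therefore come from how cells were grouped. An effect of the genotype on secretory precursors was not tested.

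Lists were also picked out because at least 80% of their members moved one way in set A and the other way in set B, with medians beyond 0.2, limits set after the medians were seen. The difference between the sets was not tested for any of them. Interferon-stimulated genes in all epithelial cells had a median of -0.24 in set A and 1.01 in set B, and all 36 members were higher in set B. MHC class II genes in all epithelial cells had -0.28 and 1.11, and in crypt cells -0.38 and 1.18, over 8 members. Stem cell genes in enterocytes had 0.65 and -0.24, and lower villus genes in crypt cells had -0.24 and 0.38.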

How the results depend on the processing

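Alternatives that combine the set term with another choice, the automatic doublet threshold and, for genes and lists, no centring within libraries were chosen after seeing the data, and the others before. The cause of each change was not tested. With 1 library left in a group, that library is assumed to vary like the others, and with the set term no residual degrees of freedom would be left, so that combination was not run. Genotype and set are then partly confounded, so changes without 1 library do not separate the weight of that library from the difference between sets. The calls of single genes depend on the set term: with the set as a replicate block 21 genes were called in all epithelial cells, 80 in crypt cells and 102 in other named classes, against 0 without it. In all epithelial cells DESeq2 called 8, and with the block the count was 33 with automatic doublets, 16 with doublets kept, 33 under 15% mitochondrial UMIs, 21 on thinned counts, 40 with DESeq2's normalization (RLE) in edgeR and 29 with DESeq2. In enterocytes it was 17 without the filter on low counts and, with the block, 9 with automatic doublets, 2 under 15% mitochondrial UMIs, 50 on thinned counts, 10 with RLE, 2 with DESeq2 and 1 without centring. In crypt cells, with the block, it was 78 (13 up, 65 down) with automatic doublets, 27 (20, 7) with doublets kept, 44 (37, 7) under 15%, 153 (79, 74) on thinned counts, 135 (72, 63) with RLE, 34 (22, 12) with DESeq2 and 86 (68, 18) without centring, against 45 up and 35 down. The crypt cells of wild type 1, 1171 or 27.5% of its cells, became 107 (2.39%) with automatic doublets, 109 (2.30%) under 50% mitochondrial UMIs and 86 (2.02%) at resolution 0.5. In other classes it was 1 with DESeq2, 457 without the filter and, with the block, 101 with RLE, 27 with DESeq2 (4 in enteroendocrine, 1 in tuft, 13 in stem-like cells) and 131 without centring (20 in enteroendocrine against 84, 71 in cycling-like against 0). Leaving out 1 library, without the block, gave 0 to 26 genes in enterocytes (26 without wild type 1, 2 without mutant 1, 3 without wild type 2), 0 to 1 in crypt cells (1 without mutant 2) and 12 to 680 in other classes (80 without wild type 1, 12 without mutant 1, 680 without wild type 2, 187 without mutant 2). These counts for other classes leave out the clusters without a name, where it was 21 without the filter, 1 without wild type 1, 4 without mutant 2 and, with the block, 75, or 26 with RLE, 4 with DESeq2 and 87 without centring.

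With an estimated correlation or with fry, 0 lists were called in all epithelial cells, enterocytes and crypt cells, with and without the block. Leaving out 1 library gave 12 to 23 lists in all epithelial cells, 10 to 18 in enterocytes and 11 to 19 in crypt cells, but with the same direction only 6 to 13 of the 20 calls, 7 to 11 of the 15 and 9 to 12 of the 18 were kept. Without centring, 13 lists were called in crypt cells (12 up, 1 down), 12 of them among the 18, and the crypt lists of endoplasmic reticulum stress (adjusted p = 0.786), goblet genes (0.483) and lower villus genes (0.977) changed direction. Without 1 library, these lists changed direction in all epithelial cells, with adjusted p ranges of 1.23e-06 to 0.629 for mtDNA-encoded mRNAs, 4.03e-06 to 0.768 for complex IV, 0.00107 to 0.839 for complex V, 6.54e-05 to 0.95 for cholesterol synthesis, 0.0378 to 0.95 for stem cell genes, 7.15e-45 to 0.466 for interferon genes, 1.14e-18 to 0.0938 for MHC class II, 4.83e-13 to 0.109 for MHC class I, 4.61e-14 to 0.55 for antimicrobial genes, 0.00012 to 0.878 for regenerative genes, 7.92e-11 to 0.42 for villus tip genes and 6.55e-09 to 0.856 for immediate early genes. In enterocytes the ranges were 0.0122 to 0.142 for mtDNA-encoded mRNAs, 1.9e-12 to 0.991 for complex I, 2.77e-17 to 0.763 for mitochondrial ribosomal proteins, 3.15e-05 to 0.557 for stem cell genes, 6.17e-12 to 0.446 for G2 and M phase genes, 5.72e-15 to 0.000158 for goblet genes and 3.48e-30 to 0.812 for cytosolic ribosomal proteins. In crypt cells they were 2.83e-27 to 0.0529 for MHC class II, 2.98e-17 to 0.169 for MHC class I and 0.0157 to 0.637 for lower villus genes. Without wild type 2 the upward crypt calls of MHC class II and MHC class I became downward calls (adjusted p = 8.49e-05 and 0.00663).

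The log2 ratios of shares, of which 0 passed the test, changed sign in several settings: tuft cells -0.0582 with the block, stem-like cells 0.99 and unnamed clusters -0.42 under 50% mitochondrial UMIs, unnamed clusters -0.0759 with doublets kept and -0.48 at resolution 0.5, and with automatic doublets stem-like cells 1.00, tuft cells -0.15 and unnamed clusters -0.57. Without 1 library they ran from -1.26 to 0.32 for enterocytes, -0.92 to 0.15 for enteroendocrine cells, -0.77 to 0.35 for goblet cells, -0.35 to 1.73 for Paneth cells, -0.55 to 0.00812 for stem-like cells, -0.66 to 0.47 for tuft cells and -0.16 to 0.69 for unnamed clusters. Resolution 2.0 gave 40 clusters. With the block mt-Nd6 had 0.0221. Without 1 library and without the block, log2 ratios in all epithelial cells ran from -0.13 to 2.66 for Acta1, -2.04 to 0.37 for Clca4a, -2.58 to 0.61 for Cyp3a11, -0.0902 to 0.45 for mt-Atp6, -0.38 to 0.72 for mt-Atp8, -0.48 to 0.22 for mt-Co1, -0.10 to 0.40 for mt-Co3, -0.0739 to 0.13 for mt-Nd2, -0.24 to 0.82 for mt-Nd4l, -0.34 to 0.25 for mt-Nd5 and -0.59 to 0.71 for mt-Nd6. In crypt cells they ran from -0.31 to 2.12 for Defa29 and from -1.45 to 0.17 for Hsph1, in tuft cells from -0.19 to 2.88 for Isg15, and in enteroendocrine cells from -0.23 to 2.59 for Ghrl and from -2.18 to 0.45 for Pyy.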

Other observations

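The results of this part were chosen after their values were seen, and the fits and tests behind them are the ones described for the other genes, with the set as a term. In enteroendocrine cells, the stem cell gene Olfm4 rose by a log2 ratio of 1.40 (SE 0.17, 1.22 in set A and 1.61 in set B), and Neurog3, the factor that starts the enteroendocrine lineage, fell by 0.83 (SE 0.17, -0.90 and -0.76). Hormone genes called in these cells moved apart by set, with Ghrl at 2.67 in set A and -0.33 in set B, Sst at 0.05 and -2.15 and Pyy at 0.46 and -2.18. In tuft cells Olfm4 rose by 1.19 (SE 0.16, 1.04 and 1.35), and the interferon-induced genes Ifitm3, Isg15 and Ddx60 rose by 1.37 (SE 0.25), 1.70 (SE 0.34) and 2.06 (SE 0.40). The ligand gene Guca2a fell by 1.43 (SE 0.22) in tuft cells and by 0.93 (SE 0.18) in enteroendocrine cells. Guca2a is a leading gene of goblet cluster 3. Goblet markers summed over all epithelial cells had -0.62 in set A and -0.44 in set B, and goblet RNA in the tuft and enteroendocrine sums was not excluded. Olfm4 and Ifitm3 are leading genes of stem-like clusters, and stem cell RNA in these sums was not excluded: Olfm4 took 4285 to 5835 CPM in crypt cells, against 180 to 1167 in tuft and 90.9 to 965 in enteroendocrine cells. The other 12 stem markers summed to log2 ratios of 0.05 in set A and -0.54 in set B in tuft cells and -0.14 and -0.31 in enteroendocrine cells. Isg15 had 5, 7, 21 and 93 UMIs and Ddx60 4, 5, 12 and 75 in the tuft cells of wild type 1, mutant 1, wild type 2 and mutant 2. In the clusters without a name, where 75 genes were called (26 with DESeq2's normalization, 4 with DESeq2 and 87 without centring, all with the set term), the stress response genes Atf5, Asns, Mthfd2 and Psph rose by 1.80 (SE 0.20), 0.92 (SE 0.16), 0.83 (SE 0.17) and 0.67 (SE 0.17). They are 4 of the 9 called among 29 members of that list, of which 20 were higher in both sets and 1 lower in both (median 0.52 in set A and 0.31 in set B), and the list as a whole was not tested in these cells. These cells came from different clusters: cluster 7 held 93.6% of those of wild type 1, cluster 19 held 98.3% of those of mutant 1, and cluster 17 held 89.0% and 93.4% of those of wild type 2 and mutant 2.

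Some calls in all epithelial cells concern genes of other cell types or near copies, and each was chosen after its values were seen. The globin genes Hbb-bs and Hba-a1 rose by 3.83 and 2.95, in cells stained for TER-119 before a sort whose gates are not given in the sources used here, and summed erythroid markers were 3.70, 25.6, 1.79 and 17.2 CPM in wild type 1, mutant 1, wild type 2 and mutant 2. The mast cell protease gene Mcpt1 had 16, 1, 64 and 0 UMIs in that order, a ratio of 0.0113 (exact 95% interval, for counting error only, 0.000283 to 0.0648). The cells were also stained for CD45 before that sort. A cluster of 13 cells, all of wild type 2, had Mcpt1 among its leading genes. On chromosome X, Xlr3b fell by 2.78 (SE 0.30) and Fmr1nb by 3.45. Xlr4b had 96, 1, 10 and 1 UMIs, a ratio of 0.0171 (0.00204 to 0.0632, likewise). These 3 genes lie between 68761839 and 73222453, where 20 genes were tested and the 17 not called ran from -2.02 to 0.46 with a median of 0.09. Xlr3b and Xlr4b have near copies, and a strain difference in this region was not tested.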
